A study of Mus musculus with 8 samples.

How the data were processed

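The deposited FPKM tables were analysed as given. According to the submitters' processing notes, reads were aligned to mouse build mm9 with TopHat and summarised with Cufflinks, without versions. The libraries were paired-end, 100 cycles, run on a HiSeq 2500, from pooled RNA of 8 Foxd1-null and 10 control embryos. The labels described the controls in a way that could be read as either genotype, so genotype was taken from the source name of each library, and the level of Foxd1 was then given for each. No table carried a column of quantification status, so the planned removal of values not marked as good could not be applied.

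The E12 table held 23737 rows and 23440 gene symbols, of which 8 rows had no gene name and carried between 0.0285% and 0.0360% of FPKM. The E17.5 table held 32952 transcript rows and 24002 symbols, and 22725 symbols were in both. Rows sharing a symbol were summed. Small RNA genes carried between 9.87% and 24.5% of FPKM per library. Because the E12 and E17.5 tables were made separately, levels were compared between genotypes within a stage and only described between stages.

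Values were taken as log2 of FPKM + 1, and genes with a mean of at least 1 FPKM over the libraries of a fit were tested with limma, with a trend of variance on mean level. Tests were two-sided and p was adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. The E17.5 comparison used 4 libraries. The E12 comparison used 4 libraries with stage as a block, the comparison over all stages used 8 libraries with stage as a block, and the difference between the genotype effects of E17.5 and E12 was tested in the same 8. Single early stages, with 1 library per genotype, were not tested. A difference of 2-fold was counted there, and list medians were placed among 10000 random lists of matched expression. FPKM without counts allowed no count model.

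The 37 gene lists were written, and the comparisons, alternatives and rule for named genes were set, before the data were examined. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, then with camera at an estimated correlation and with fry. With an estimated correlation camera uses the residual degrees of freedom of the fit. These were 2 at E17.5, 1 at E12, 4 over all stages and 3 for the difference. A call can therefore be lost there whatever the correlation. List tests of the difference between stages were added after the data were seen, as were the alternatives with small RNA genes left out, with robust spread and with both E12.0 libraries left out. The other alternatives changed the pseudocount, the filter, the normalization, the trend, the way rows were joined, the blocks and the libraries used, and the closing section gives their effect. Single members were adjusted over the list alone and over all genes.

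Named genes followed a rule. Foxd1 was given in every library. At E17.5 and E12 the 12 largest changes in each direction that passed the adjusted threshold were named, filled up with the largest changes at unadjusted p under 0.05 in which all libraries lay on the same side, for which only values are given. Over all stages the limit was 10 per direction and for the difference between stages 5. From each list discussed the members with the largest change were named. Predicted genes, accession-like names, small RNA genes and sex-linked genes were skipped, and some genes that the rule names are not reported here.

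In simulated data made with the same designs, and with variances drawn from the fitted prior, no gene was called in any comparison when no change was put in. With each gene's fitted variance kept, 35 genes were called at E12 with no change put in, 23 of them small RNA genes, and 6 at E17.5, 3 of them small RNA genes. The calls at E12 and at E17.5 were therefore read with caution.

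Depth was estimated from rows of a single transcript longer than 2500 nt, with a fragment length of 170 nt taken off, by finding the FPKM of 1 fragment. The low values up to 5 fragments lay within 0.1 of a whole number in 79.4% to 80.6% of cases at E17.5 and in 31.4% to 40.4% at E12, so the estimate was firm only at E17.5. Transcript length and GC content came from a GENCODE mouse annotation of a later build and were used for nothing else. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.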

Results

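RNA of embryonic mouse hypothalamus was sequenced at 3 stages (E17.5 and, earlier, E12.0 and E12.5) from wild-type embryos and embryos mutant for Foxd1. This gene encodes a forkhead transcription factor, and the comparison asks whether its loss alters the neurons that form in the anterior hypothalamus. Of the 8 libraries, 4 were wild-type and 4 mutant, with 1 library per genotype at each of the early stages and 2 per genotype at E17.5. Each library was made from pooled embryos. The stages were taken from the source names, while the submitters' account of how embryos were grown mentions just the later 2, so whether E12.0 was a separate collection is not settled. The E12 count depends on it, with 4 genes past the threshold with stage as a block and 78 without. The deposited FPKM values listed between 11572 and 13219 genes at 1 FPKM or more per library. Depth, estimated from the steps between the lowest FPKM values, was 34.7 and 43.3 M fragments in the wild-type and 40.7 and 30.4 M in the mutant libraries at E17.5. The same estimate was less certain at E12, where it gave 4.02 M for wild-type and 17.3 M for mutant at E12.0, and 57.2 M and 12.8 M at E12.5. Whether the pools were independent litters was not given, so p-values at E17.5 measure the spread between these libraries. At E12, without replicates, they measure how far the genotype difference disagreed between E12.0 and E12.5. The tests over all stages and of the difference between stages mix both kinds of spread.

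Foxd1 itself was low in every mutant library. Its FPKM was 24.95 in wild-type and 2.77 in mutant at E12.0, 30.3 and 2.50 at E12.5, and 3.90 and 1.96 against 0.396 and 0.230 at E17.5. Wild-type levels were 9.02, 12.1 and 9.34 times those of the mutant at the successive stages. All 8 libraries lay on the side that their label gives.

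**Figure D1:**
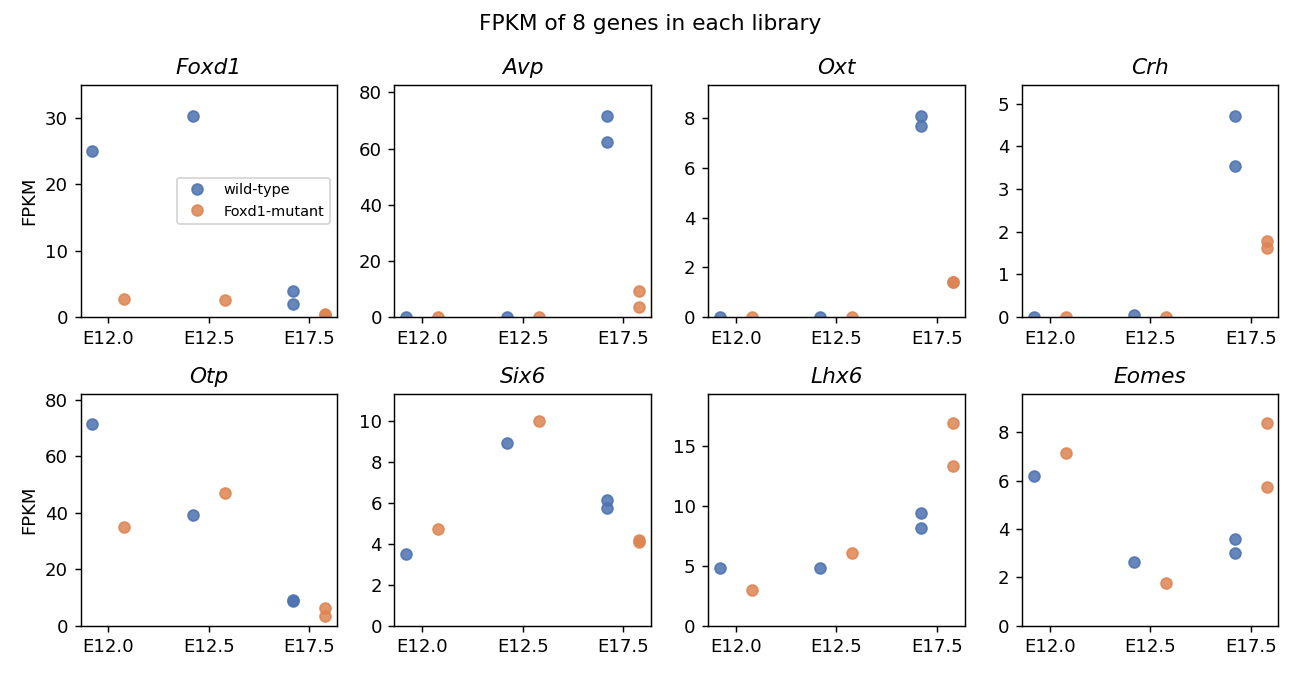
FPKM of 8 genes (y axes, linear, from 0) at the 3 stages (x axes), each point a library, wild-type in blue and Foxd1-mutant in orange; the E12 and E17.5 values come from tables made separately. Avp was at 71.6 and 62.1 FPKM in the wild-type and 9.38 and 3.43 FPKM in the mutant libraries at E17.5, while Foxd1 was lower in the mutant at each stage.

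At E17.5 Oxt, Avp and Crh, peptide genes of the paraventricular and supraoptic nuclei, were lower in both mutant libraries than in both wild-type libraries. Oxt, the oxytocin precursor, fell from 7.91 ± 0.269 to 1.41 ± 0.0255 FPKM (mean ± SD, n = 2 per genotype), a log2 change of -1.89 with a standard error of 0.0743 (limma adjusted p = 0.00716). It was the only gene of 13235 that passed the adjusted threshold. Avp, the vasopressin precursor, was at 66.9 ± 6.66 FPKM in wild-type and 6.40 ± 4.21 in mutant, a 10.4-fold difference. Crh, the precursor of corticotropin-releasing hormone, was at 4.13 ± 0.820 and 1.69 ± 0.117 FPKM. Among the 9 measured members of the paraventricular and supraoptic list, 7 were lower in the mutant. Adjusted over the list alone, 5 fell: Oxt, Avp, Crh and the transcription factor genes Otp (log2 change -0.77) and Sim1 (-0.28), both needed for these neurons to form, and over all genes 1 fell. The thyrotropin-releasing hormone and somatostatin precursors differed little, with log2 values of 0.19 for Trh and 0.06 for Sst. The list was lower as a group by limma's camera (adjusted p = 5.03e-07), a call that was lost at adjusted p = 0.805 with an estimated correlation. That estimate was 0.0101, close to the preset 0.01, and camera gave an unadjusted p of 0.0309 with it. The loss thus reflects the 2 residual degrees of freedom used in that setting, and is no check on correlation. The call on Oxt at E17.5 was lost without wild-type replicate 1 (adjusted p = 0.0534), without wild-type replicate 2 (adjusted p = 0.0793) and with no filter on low values (adjusted p = 0.0901), at log2 changes between -1.92 and -1.86. A filter at a mean of 5 FPKM left Oxt untested.

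Most measured members of 4 other hypothalamic lists had lower values in the mutant at E17.5. Of the 10 transcription factors of the suprachiasmatic nucleus, the seat of the circadian clock, 8 were lower in the mutant. Adjusted over the list alone, 1 fell, Six6, from 6.14 and 5.73 to 4.08 and 4.16 FPKM, and none over all genes. In the ventromedial list 10 of 14 members were lower. Adjusted over the list alone, Fezf1 (-0.57), Nr5a1 (-0.52), the tachykinin precursor Tac1 (-0.39) and Nptx2 (-0.37) fell, and none did over all genes. Fezf1 and Nr5a1 are regulators of the ventromedial nucleus. The mammillary list was lower in 12 of 16 members, led by Nkx2-4 (-0.68) and Uncx (-0.50), with none past the adjustment over the list alone. In the list of suprachiasmatic peptides, receptors and signalling genes 7 of 9 were lower, and Avp, which is also a member of the paraventricular list, was the 1 gene that fell adjusted over the list alone. Camera called these 4 lists lower (adjusted p = 0.00593, 0.0233, 0.0233 and 0.0422, in the order given), and each had adjusted p = 0.805 with an estimated correlation. All 4 calls were lost without mutant replicate 1 (adjusted p = 0.200, 0.294, 0.249 and 0.249). Those of the mammillary and the peptide list were lost also without wild-type replicate 2 (adjusted p = 0.299 and 0.0754).

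Telencephalic and ventral forebrain genes were higher in the mutant at E17.5. Eomes, a marker of intermediate progenitors of the cortex, was at 3.30 ± 0.394 FPKM in wild-type and 7.07 ± 1.88 in mutant. The 12 measured telencephalon markers all had positive log2 values, with a median of 0.59. Adjusted over the list alone Eomes (0.89) rose, and none did over all genes. Of 15 regulators of GABAergic neurons of the Dlx and Isl1 class 11 were higher. Adjusted over the list alone Lhx6, a regulator of interneurons, rose from 8.17 and 9.38 to 13.4 and 16.9 FPKM, and Dlx1 (0.32) and Dlx5 (0.26) rose as well, while none did over all genes. Camera called both lists higher (adjusted p = 5.44e-05 and 0.00335), and each had adjusted p = 0.805 with an estimated correlation. The estimate was 0.879 for the telencephalon list and 0.0718 for the Dlx and Isl1 class, against the preset 0.01. The 2 mutant pools differed: the cortical neuron gene Neurod6 was at 8.59 FPKM in replicate 1 and 33.7 in replicate 2, against 8.48 and 11.1 in wild-type. Over all tested genes mutant replicate 1 had Pearson correlations of 0.993 and 0.992 with the wild-type libraries. Mutant replicate 2 had 0.988 and 0.987 with them and 0.987 with mutant replicate 1. Small RNA genes carried 9.87% of its FPKM, against 13.9% to 14.7% in the other E17.5 libraries. Without mutant replicate 2 the mean log2 change of the telencephalon list was 0.08 (adjusted p = 0.951). Among 8 preoptic markers Moxd1 (0.70) rose adjusted over the list alone and none did over all genes, and the list was not called (adjusted p = 0.337).

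All 25 proliferation genes had positive log2 values at E17.5, with a median of 0.17, among them Mki67 (0.34), the cyclin gene Ccnb2 (0.34) and the topoisomerase gene Top2a (0.24). None rose adjusted over the list alone or over all genes. Camera called the list higher (adjusted p = 5.03e-07), with adjusted p = 0.805 with an estimated correlation. That estimate was 0.903, far above the preset 0.01, and camera gave an unadjusted p of 0.321 with it. The preset p thus assumed members far less correlated than these. Without mutant replicate 2 the mean log2 change of the list was 0.04. In lists of other tissues and of glia, 14 of 15 meningeal and mesenchymal genes were higher, led by the matrix proteoglycan genes Dcn (0.74) and Lum (0.55), as were 11 of 12 endothelial genes, led by Ramp2 (0.26). All 8 skeletal muscle genes and 10 of 12 oligodendrocyte lineage genes were lower, with the largest differences in Acta1 (-0.47) and Mag (-0.31). No member of these 4 lists passed the adjustment over the list alone or over all genes. Camera called them (adjusted p = 0.000253, 0.00505, 0.00702 and 0.0162), each with adjusted p = 0.805 with an estimated correlation. The estimates were 0.833, 0.497, 0.668 and 0.198 in the same order, all above the preset. The meningeal, endothelial and muscle calls were lost without wild-type replicate 2 (adjusted p = 0.182, 0.230 and 0.403) and without mutant replicate 1 (adjusted p = 0.294, 0.335 and 0.294). The oligodendrocyte call was lost without mutant replicate 2 (adjusted p = 0.158).

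**Figure D2:**
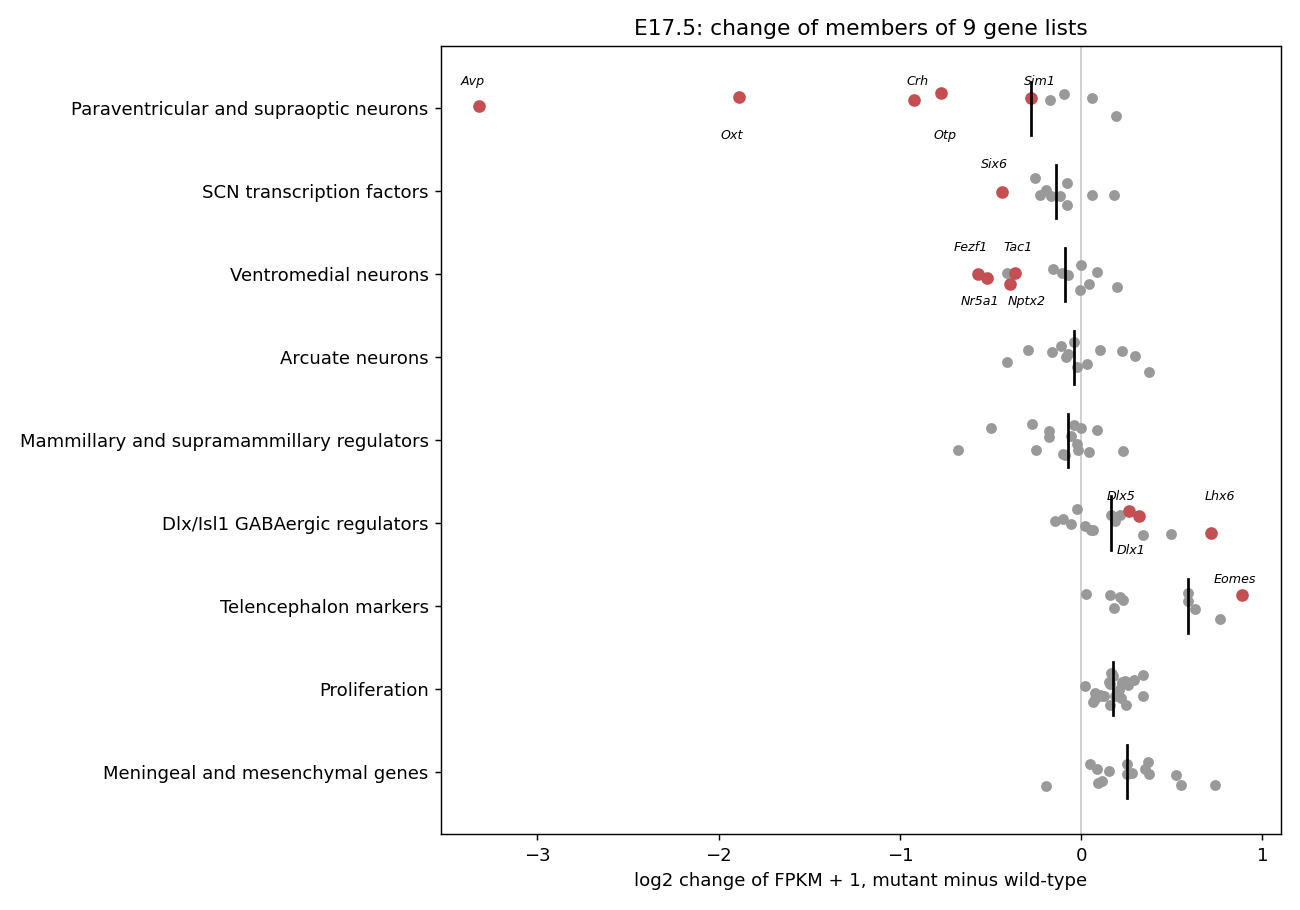
Log2 change of FPKM + 1 from wild-type to Foxd1-mutant at E17.5 (x axis) for the members shown of 9 gene lists (y axis); red points passed the adjustment over the list alone, grey points did not, named in order from left to right above and below in turn, and black bars are medians of all measured members. The paraventricular and supraoptic list spans from -3.32 (Avp) to 0.19 (Trh), while the 25 proliferation genes all lie above 0.

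By the rule for named genes the other large differences at E17.5 were lower values of Gsc (1.74 ± 0.0568 to 0.294 ± 0.137 FPKM) and Vax1 (5.26 ± 0.104 to 2.28 ± 0.419), both homeobox genes, and of Slc6a3 (2.31 ± 0.851 to 0.736 ± 0.00531), the dopamine transporter gene. Lower values were also found for the noncoding RNA genes Snhg9 (log2 -1.15) and Terc (-0.86) and for Nptxr (-0.76). Higher values were found for Tbr1 (0.63), Tbx18 (0.60), the smooth muscle actin gene Acta2 (0.60), the sulfate transporter gene Slc13a4 (0.57) and Dynlt1b (0.71), which has near-identical copies and is uncertain. None of these passed the adjustment over all genes. Slc6a3 fell adjusted over the list of transmitter genes alone, of which 8 of 12 were lower (camera adjusted p = 0.0746). At unadjusted p under 0.05 limma gave 755 of the 13235 genes, 289 higher and 466 lower, where chance gives 662. In simulated data with the same design and variances drawn from the fitted prior, 98% of genes changed by 1 log2 unit and 100% of those changed by 2 were recovered. That simulation changed 100 genes by each amount, which eases the adjusted threshold, so its rates do not give the power of the real test. With no change put in, it called no gene, while 6 were called when the fitted variance of each gene was kept. The single call on Oxt is thus no more than that second setting gave. In the real fit Avp (-3.32, limma adjusted p = 0.585) and Foxd1 (-1.54, 0.689) did not pass.

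Camera called none of the other lists at E17.5. The arcuate list, with Npy and Pomc, had 5 of 13 members higher (adjusted p = 0.710). The dorsomedial and lateral list had 5 of 10 higher (adjusted p = 0.830), with the orexin precursor Hcrt at 9.12 and 7.57 FPKM in wild-type and 5.74 and 3.91 in mutant. Thalamus and prethalamus markers were lower in 9 of 12 (adjusted p = 0.0714). Adjusted p was 0.756 for circadian clock genes, 0.203 for neural progenitors, 0.948 for pan-neuronal genes, 0.441 for astrocyte and tanycyte genes, 0.948 for the Sonic hedgehog pathway, 0.987 for the Wnt pathway, 0.948 for the FGF and BMP pathways and 0.756 for immediate early genes. For other tissues it was 0.199 for pituitary, 0.578 for eye, 0.845 for red blood cells, 0.439 for pericytes and smooth muscle, 0.948 for cartilage, 0.240 for microglia and macrophages, 0.627 for choroid plexus and 0.210 for surface epithelium. Adjusted p was 0.430 for hypoxia and glycolysis, 0.108 for sex-linked genes and 0.845 for forkhead genes, and mitochondrially encoded genes had no members in the tables used here. In the eye list Crybb1 and Rlbp1 fell adjusted over the list alone, and among forkhead genes Foxd1 fell.

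At E12 the 2 early stages were tested together, with stage as a block, for the mean genotype difference of both. Foxd1 fell (log2 change -2.97, standard error 0.156, limma adjusted p = 0.0305). Hist1h2ba, a histone H2B variant gene best known from testis, rose by 6.34 on the log2 scale (adjusted p = 0.000984). It was listed at 1.01 FPKM in wild-type and 176 in mutant at E12.0, and at 1.74 and 204 at E12.5. It is among 16 listed H2B genes of closely similar sequence, so its level is uncertain. The other 2 of the 4 genes past the threshold, of 11952 tested, were chosen for mention after their values were seen. Gm12238, a predicted gene, was listed at 0 in both wild-type libraries and at 33.8 and 19.3 FPKM in the mutant, and the small nucleolar RNA gene Snord34 was listed at 4665 and 766 FPKM in wild-type and at 0 in both mutant libraries. At unadjusted p under 0.05 limma gave 168 genes, 72 higher and 96 lower, where chance gives 598. The call on Foxd1 at E12 was lost with pseudocount 5 (adjusted p = 0.0865), no filter (0.0547), quantile normalization (0.104), no trend (0.0668), spread from all libraries (0.0577) and without either E12.0 library (0.149 and 0.138), at log2 changes from -3.16 to -2.09. That on Hist1h2ba at E12 was lost without the wild-type or mutant E12.0 library (adjusted p = 0.0856 and 0.0801). The fit has 1 residual degree of freedom, and in simulated data with variances drawn from the fitted prior it recovered 55% of genes changed by 1 log2 unit and 97% of those changed by 2, against 91% and 100% with the fitted variance of each gene. These simulations changed 100 genes by each amount, so the rates do not give the power of the real test. With no change put in they gave 583 and 578 genes at unadjusted p under 0.05, unlike the 168 of the real fit.

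Among the other genes named by rule at E12, none passed the adjusted threshold. Six3, a regulator of the anterior forebrain, was at 14.2 and 3.27 FPKM in wild-type and mutant at E12.0 and at 4.68 and 3.73 at E12.5. Tcf7l2, a Wnt effector abundant in thalamus, was at 17.6 and 14.9 and then at 19.6 and 4.90, and Tbr1, a cortical neuron regulator, had a log2 change of -0.76. Lower at both stages were also Atp1b2 (log2 -0.98), Cdk5r2 (-0.98), Kif2a (-0.83), Fign (-0.80), Tram2 (-0.78), Hist1h2bf (-1.20) and the antisense gene Tsix (-0.75). Higher at both stages were Lars2, listed at 0 and 286 FPKM at E12.0 and at 1825 and 5076 at E12.5, Acyp2 (1.22), Lockd (1.06), Rangrf (0.98), Toporsos (0.93), Pop4 (0.88) and Eno1b (0.93), a near copy of Eno1. The replication-dependent histone genes Hist1h2an (1.14), Hist1h4c (0.86), Hist1h2ag (0.77) and Hist1h2bj (0.74) were higher as well. Values of near-identical histone genes, of Eno1b and of antisense genes such as Tsix and Toporsos are uncertain. So are those of Lars2 (log2 change 4.82, standard error 1.51), which differed widely between the 2 early wild-type libraries.

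Gene groups at E12 were called on the same fit. All 25 proliferation genes had positive log2 values (median 0.18), among them the spindle checkpoint gene Cdc20 (0.29) and Aurka (0.27). Of 17 pan-neuronal genes 16 were lower, led by the synaptic gene Syn1 (-0.99) and the migration gene Dcx (-0.54). All 12 thalamus and prethalamus markers were lower, led by Tcf7l2 (-1.01) and Gbx2 (-0.83), as were 13 of 16 regulators of the Dlx and Isl1 class, including Dlx5 (-0.55) and Meis2 (-0.48), and 7 of 9 suprachiasmatic transcription factors, including Six3 (-1.05) and Zfhx3 (-0.80). No member of these 5 lists passed the adjustment over the list alone or over all genes. In the sex-linked list the Y-linked genes Eif2s3y, Uty, Kdm5d and Ddx3y rose and Xist fell adjusted over the list alone, and none did over all genes. The median of that list was 0.40 at E12.0 and 0.42 at E12.5, so the sexes may not have been balanced between the E12 pools. Tsix was not on it, so the rule for named genes did not skip Tsix. Camera adjusted p was 8.57e-08, 5.97e-05, 0.000212, 0.00165, 0.00657 and 0.00190 for the 6 lists in the order given, and each had adjusted p = 0.666 with an estimated correlation. With both E12.0 libraries left out, an alternative added after seeing the data, the calls of pan-neuronal genes (adjusted p = 0.0744), of the Dlx and Isl1 class (0.991), of suprachiasmatic factors (0.414) and of sex-linked genes (0.873) were lost and 51 genes passed the threshold. In the fit of all libraries, which gave 3 genes with none left out, leaving out the wild-type or mutant library gave 49 and 51 genes at E12.0 and 2414 and 2276 at E12.5, and a stage left with a single library there gives no genotype difference. With none left out that fit already lost the calls of SCN transcription factors at E12 (adjusted p = 0.130) and Sex-linked genes at E12 (0.877). Without the wild-type or mutant E12.5 library the thalamus list turned to a mean of 0.13 (adjusted p = 0.874 and 0.887), and the proliferation call was lost (0.325 and 0.343). Camera called no other list at E12, the closest being telencephalon markers (adjusted p = 0.0517) and forkhead genes (0.0617), and the cartilage collagen gene Col2a1 (0.61) rose adjusted over its list alone.

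Taken singly the 2 early stages had 1 library per genotype, so their differences have no replicate check. At E12.0 302 of 11630 genes differed by at least 2-fold, 78 higher and 224 lower in the mutant, and at E12.5 87 of 12151 did, 21 higher and 66 lower. Across genes, which are not independent replicates, the log2 differences of the 2 stages had a Pearson correlation of 0.0403 and a Spearman correlation of -0.0622 with small RNA genes left out. At E12.0 the Dlx and Isl1 class had a median log2 difference of -0.55, with 14 of 15 members lower, below all 10000 random lists of matched expression, with Dlx5 at 33.3 FPKM in wild-type and 14.3 in mutant, while at E12.5 its median was -0.0125, with 8 higher and 8 lower (percentile 32.9). Suprachiasmatic transcription factors had a median of -0.50, with 7 of 9 lower and pan-neuronal genes -0.28 (percentile 0.0800). The random lists were not matched on transcript length, which the E12.0 difference followed (Spearman correlation -0.349). At E12.5 the thalamus and prethalamus markers had a median of -0.56, with 12 of 13 lower, again below all random lists, while at E12.0 their median was -0.0359, with 6 higher and 6 lower (percentile 31.4). Gbx2 was at 8.20 FPKM in wild-type and 0.630 in mutant at E12.5, Shox2 at 6.04 and 0.597, Olig3 at 7.74 and 2.80, and Lhx9 at 9.99 and 3.37. At E12.0 the order was the opposite for Gbx2 (0.954 and 2.48) and Shox2 (0.466 and 4.66). Proliferation genes had a median of 0.19 at E12.0, with 22 of 25 higher, and of 0.21 at E12.5, above all random lists, where all 25 members were higher. Mammillary regulators had a median of -0.27 at E12.0 (percentile 0.0800) and of 0.13 at E12.5, above all random lists.

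**Figure D3:**
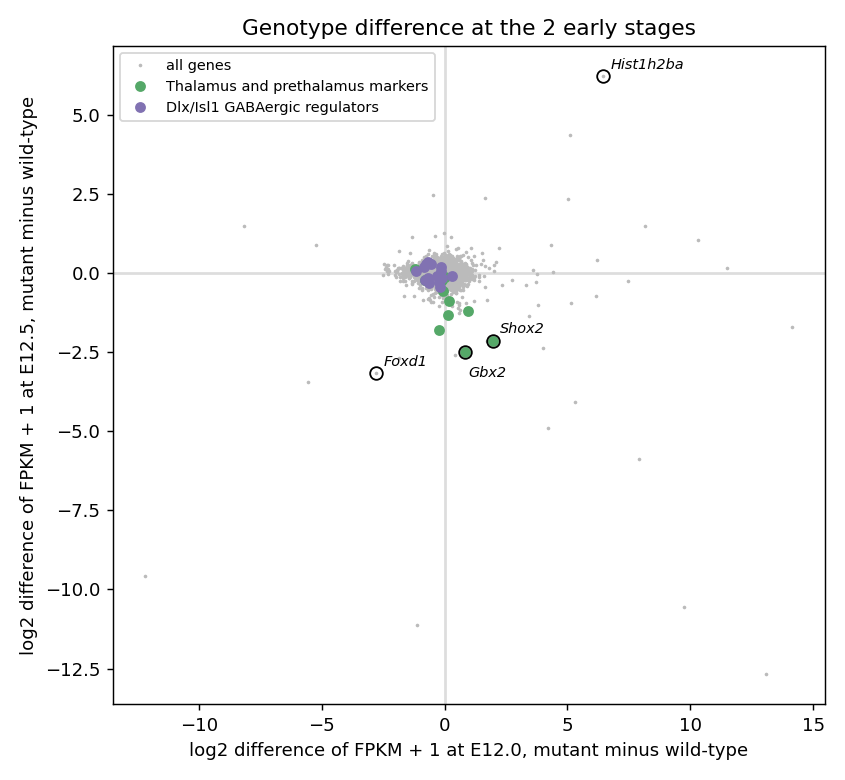
Log2 difference of FPKM + 1, mutant minus wild-type, at E12.0 (x axis) and at E12.5 (y axis) for 11530 genes (grey points), with thalamus and prethalamus markers in green, regulators of the Dlx and Isl1 class in purple and 4 genes circled. Foxd1 lies at -2.78 and -3.16, and Gbx2 at 0.83 and -2.50; 1 library per genotype stands behind each axis.

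Over all 3 stages, with stage as a block, the test asked for the mean genotype difference, which a single stage can carry. No gene of 12519 passed the adjusted threshold in limma, and 695 had an unadjusted p under 0.05, 306 higher and 389 lower, where chance gives 626. In simulated data with this design and variances drawn from the fitted prior 93% of genes changed by 1 log2 unit and 98% of those changed by 2 were recovered. Here too 100 genes were changed by each amount, so the rates do not give the power of the real test, in which Foxd1 (-2.25) did not pass. Among gene lists, all 25 proliferation genes were higher (median 0.19). Lower were all 17 pan-neuronal genes (median -0.08), 8 of 9 paraventricular and supraoptic genes, all 13 thalamus and prethalamus markers, all 10 suprachiasmatic transcription factors, led by Six3 (-0.58) and Zfhx3 (-0.44), 10 of 13 ventromedial genes, led by Sox14 (-0.39), 5 of 5 skeletal muscle genes and 9 of 11 oligodendrocyte genes. Neither adjusted over the list alone nor over all genes did a member of these 8 lists pass. In lists that were not called, Pmch (0.32) rose and Nptx1 (-0.24), Nkx2-2 (-0.39), Rlbp1 (-0.32) and Foxd1 (-2.25) fell adjusted over the list alone, and none did over all genes. Camera adjusted p lay between 1.25e-13 for proliferation and 0.0392 for the last 2 lists, and was between 0.564 and 0.587 for the 8 lists with an estimated correlation. The estimates ran from -0.0543 for ventromedial genes to 0.649 for proliferation, so the preset p of proliferation assumed far less correlated members. With both E12.0 libraries left out, adjusted p was 0.344 for pan-neuronal genes, 0.0703 for the list Oligodendrocyte lineage over all stages and 0.0542 for muscle genes, so those calls were lost. Without the wild-type E12.5 library the mean of the thalamus list was 0.01 (adjusted p = 0.491), and without the mutant one 0.01 (adjusted p = 0.480).

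The last test asked whether the genotype difference itself differed between E17.5 and E12, over the same 12519 genes. Oxt passed (log2 difference of the differences -1.89, limma adjusted p = 0.0466), but it was listed at 0 in all 4 E12 libraries, so this value repeats its E17.5 change. Hist1h2ba passed too (-6.82, adjusted p = 0.0466), since at E17.5 it was at 21.2 and 13.6 FPKM in wild-type and 18.1 and 7.69 in mutant. The other 2 of 4 genes, named after their values were seen, were Gm12238 and Snord34, both listed at 0 in every E17.5 library. At unadjusted p under 0.05 limma gave 494 genes, 218 higher and 276 lower, where chance gives 626. The call on Oxt in the interaction was lost without wild-type replicate 1 or 2 of E17.5 (adjusted p = 0.440 and 0.378) or mutant replicate 1 or 2 (0.280 and 0.467), with pseudocount 0.1 (0.724), no filter (0.0530), quantile normalization (0.149) and the highest row per symbol (0.0534), and a filter at a mean of 5 FPKM left it untested. The call on Hist1h2ba in the interaction was lost without the same libraries (0.158, 0.123, 0.0537 and 0.167) and without the wild-type or mutant E12.0 library (0.151 and 0.143). It was lost also with pseudocount 0.1 (0.0647), pseudocount 5 (0.0685), no filter (0.233), a mean of at least 5 FPKM (0.0647), quantile normalization (0.0691), no trend (0.0714), the highest row per symbol (0.0534) and robust spread (0.471). With a replicate block only 1 gene passed, so at least 1 of the calls on Oxt and Hist1h2ba was lost there as well. Lists were tested for this difference after the data were seen. Camera gave a more positive difference at E17.5 for the Dlx and Isl1 class (mean 0.34, adjusted p = 0.000738), pan-neuronal (0.25, 0.000738), meningeal (0.43, 0.000738), telencephalon (0.59, 0.00141) and endothelial genes (0.21, 0.00455), and a more negative difference for paraventricular and supraoptic genes (-0.72, 0.00201). That negative mean was carried by Avp (-3.26), Oxt (-1.89) and Crh (-0.89). All were at 0.0892 FPKM or less at E12, so it largely repeats their E17.5 change. With an estimated correlation adjusted p was 0.920 for 5 of these lists and 0.925 for meningeal genes. Without the wild-type E12.0 library 4 calls were lost, those of Dlx/Isl1 GABAergic regulators in the interaction (mean 0.16, adjusted p = 0.0585), Pan-neuronal genes in the interaction (0.08, 0.101), Telencephalon markers in the interaction (0.34, 0.266) and Meningeal and mesenchymal genes in the interaction (0.30, 0.111). Without the wild-type E12.5 library those of Paraventricular and supraoptic neurons in the interaction (-0.60, 0.711) and Endothelial genes in the interaction (0.23, 0.384) were lost, and that of meningeal genes again (0.0754). In simulated data with variances drawn from the fitted prior 48% of genes changed by 1 log2 unit and 92% of those changed by 2 were recovered, against 74% and 99% with the fitted variance of each gene. Again 100 genes were changed by each amount, so the rates do not give the power of the real test.

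Wild-type levels were described by stage without a test, because the E12 and E17.5 tables were made separately and may not share a scale. Foxd1 was at 24.95 and 30.3 FPKM at E12.0 and E12.5 and at 3.90 and 1.96 at E17.5. Otp was at 71.2, 39.2, 8.90 and 8.60 FPKM in the 4 wild-type libraries in the same order, and Mki67 at 30.2, 17.3, 5.87 and 5.68. The neuronal gene Snap25 was at 12.8, 26.8, 91.6 and 93.3 FPKM and Calb2 at 7.83, 13.3, 93.7 and 93.5. The peptide genes Avp, Oxt, Crh and Hcrt were at most at 0.137 FPKM in the 2 E12 wild-type libraries, while Pmch, the precursor of melanin-concentrating hormone, was at 5.81 and 26.2 FPKM there.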

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

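All tests of explanations in this part were chosen after the result was seen, except that of slower maturation, which was written before.

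The genotype difference at E17.5 differed from that at E12 for Oxt by -1.89, Hist1h2ba by -6.82, Gm12238 by -4.73 and Snord34 by 10.89 on the log2 scale. It differed by a mean of -0.72 for paraventricular and supraoptic genes, carried by Avp (-3.26), Oxt (-1.89) and Crh (-0.89). These genes were at 0.0892 FPKM or less in the E12 libraries, so their values largely repeat the E17.5 change. Of the other members Trh (-0.49), Sim1 (-0.40) and Otp (-0.39) were lower, and Sst (0.57), Arnt2 (0.26) and Pou3f2 (0.02) higher. The mean was 0.34 for the Dlx and Isl1 class, 0.25 for pan-neuronal genes, 0.59 for telencephalon markers, 0.21 for endothelial genes and 0.43 for meningeal genes. All 6 list calls were lost at adjusted p = 0.920 (0.925 for meningeal genes) with an estimated correlation, and each was lost without the wild-type E12.0 or the wild-type E12.5 library. With an estimated correlation camera has 3 residual degrees of freedom here, so a call is hard to reach. The estimates ran from 0.0570 for paraventricular and supraoptic genes to 0.664 for meningeal genes, so correlation of the members weakened some calls as well.

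Telencephalon markers were higher in the mutant at E17.5. Cortical tissue added to 1 mutant pool is a likely part of it, since the median difference of the 12 markers from the wild-type mean was -0.11 in mutant replicate 1 and 0.87 in replicate 2, where Neurod6 was at 33.7, Lhx2 at 13.7 and Bcl11b at 12.4 FPKM. Cortical tissue in both pools met the rule written against it, since 4 cortical markers had a median of -0.23 in replicate 1, against 1.52 in replicate 2. It was left open beyond that rule because Tbr1, which is among the 4, and Eomes were higher in both. More septal, preoptic or ventral telencephalic tissue in both pools may contribute, since Lhx6, Lhx8 and Moxd1 were higher in both. Only a minority, 8 of 22 members of the Dlx and Isl1 and preoptic lists (36.4%), lay above both wild-type libraries in both mutant pools. By the rule written for it this counts against it, and it was left open beyond that rule because the other members were not all lower. Of the 12 markers, 4 are held by other lists.

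Oxt, Avp and Crh were lower in the mutant at E17.5. Dilution of hypothalamic RNA by other tissue was excluded as the whole cause, since 52 genes of 5 other hypothalamic lists had a median log2 change of -0.0814 with quartiles of -0.19 and 0.05. A small dilution could give such a median and was not excluded. Slower maturation was not settled by its test. The 10 genes at least 16-fold higher at E17.5 than at E12.5 had a median of -0.19, which met the rule written for it. They were picked across tables that may not share a scale, so they cannot show maturation alone. Those 10 included ribosomal and small RNA, choroid plexus and pituitary genes, and a set of 395 genes at least 4-fold higher, added after the first value was seen, had a median of -0.03, which leaves it open. Fewer paraventricular and supraoptic cells may be part of it, since 4 transcription factors of the region had a median of -0.22, with Otp lowest at -0.77, though these are expressed elsewhere too and Trh and Sst were not lower.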

How the results depend on the processing

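Alternatives changed 1 choice, and each library was left out in turn, which assumes that the remaining library of its group has the spread of the others. At E12 the fits with libraries left out took their spread from all remaining libraries of the 3 stages, so they changed 2 choices, and the matching fit with every library gave 3 genes. At E17.5 the count of genes was 1 and became 0 with no filter, 0 at a mean of at least 5 FPKM, which removed Oxt, and 16 with a replicate block. The block was not used since deviations of libraries with the same number had a correlation of 0.0280 over 13235 genes. At E12 the count was 4 and became 1 with pseudocount 5, 1 with no filter, 1 with quantile normalization, 1 with no trend, 78 with no stage block and 51 with both E12.0 libraries left out. Over all stages it was 0 throughout. For the difference between stages it was 4 and became 1 with pseudocount 0.1, 1 with pseudocount 5, 0 with no filter, 0 at a mean of at least 5 FPKM, 1 with quantile normalization, 2 with the highest row per symbol, 2 with robust spread, 1 with a replicate block and 48 with both E12.0 libraries left out. Gene lists were called 12 times at E17.5, 6 at E12, 8 over all stages and 6 for the difference, and 0 in each with an estimated correlation and 0 with fry. With an estimated correlation camera has 1 to 4 residual degrees of freedom, so a call is hard to reach there. The estimate itself weakened some calls too. Over all stages camera gave proliferation an unadjusted p of 3.48e-15 at the preset correlation and 0.0971 at the estimate of 0.649. For suprachiasmatic transcription factors, with an estimate of -0.00672, it gave 0.00128 and 0.0282. With no stage block 1 list was called at E12, and at a mean of at least 5 FPKM 5 were called over all stages. At E12.0 the count of 2-fold genes was 302 and became 510 with pseudocount 0.1. With a library left out the counts ran from 1 to 44 at E17.5 (lists 6 to 19), 49 to 2414 at E12 (2 to 6), 0 to 0 over all stages (5 to 10) and 0 to 1465 for the difference (2 to 10). Without either E12.5 library the mean of Thalamus and prethalamus markers at E12 turned to 0.13, against -0.86 without the wild-type E12.0 library. The direction of camera, which weighs members by their spread, turned in 2 lists whose mean shrank without changing sign. These were Dlx/Isl1 GABAergic regulators at E12 without either or both E12.0 libraries (mean -0.00832, against -0.36 without the wild-type E12.5 library) and Sex-linked genes at E12 without either E12.5 library (0.11, against 0.35 without the wild-type E12.0 library). Of 366 values of 24 named genes at E17.5, 347 stayed the same, 16 were stronger and 3 weaker. Of 392 values of 24 genes at E12, 346 stayed, 35 were stronger and 11 weaker, and of 39 values of 2 genes for the difference 15 stayed and 24 were weaker. For lists 170 of 191 values stayed at E17.5, 75 of 102 at E12 with 7 reversed, 134 of 159 over all stages and 95 of 120 for the difference. The cause was not tested.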

Other observations

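The tests of depth, of GC content and transcript length and of the place of the wild-type E12.0 library were written before their results, and the splits of the libraries were among the tests chosen after.

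Tissue beside the hypothalamus varied between pools at E17.5. Ttr, which marks choroid plexus, was at 49.99 and 133 FPKM in the wild-type and 4.76 and 333 in the mutant libraries. The pituitary hormone genes Gh (59.4 and 15.5 against 35.8 and 41.0), Tshb (8.84 and 2.51 against 7.09 and 13.1) and Pomc (38.9 and 11.3 against 18.6 and 41.4) varied as much within a genotype. The Y-linked gene Eif2s3y was listed at 0 in wild-type replicate 1 and at 10.6 FPKM in wild-type replicate 2, against 14.0 and 8.56 in the mutant, so the sexes were not balanced between pools. Among other peptide genes, Pmch was at 54.0 and 55.8 against 65.1 and 56.2 FPKM, Ghrh at 5.15 and 4.67 against 4.73 and 4.76, and Hcrt at 9.12 and 7.57 against 5.74 and 3.91.

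Differences of 2-fold were far more frequent at E12.0 than at E12.5. Low depth of the wild-type E12.0 library was excluded as the whole cause, since among genes with a mean of at least 10 FPKM 154 of 5849 differed at E12.0 and 52 of 6843 at E12.5. A bias of GC content or transcript length was likewise excluded as the whole cause of this count, since 264 genes remained at E12.0 and 84 at E12.5 after both trends were taken out, from 294 and 86. The E12.0 difference did follow transcript length, with longer transcripts lower in the mutant (Spearman correlation -0.349, against 0.113 at E12.5). List differences at E12.0 may carry this trend, which was not tested. The wild-type E12.0 library likely stood apart, since in 252 of 302 genes (83.4%) the mutant E12.0 library lay nearer the E12.5 mean. Stage or dissection of that pool could each give this, and leaving both E12.0 libraries out gave a mean of -0.01 for the Dlx and Isl1 class at E12.

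The 8 libraries could be split in 34 ways with stage as a block, the real one included. The real split gave 0 genes, which all 34 reach whatever the data, so the splits decide nothing about genes, and the highest of the others gave 2. For gene lists 17 of 34 gave as many as the real 8, and the highest of the others gave 15. Many splits put both libraries of an early stage on 1 side, unlike genotype, which is balanced within each stage. Among splits balanced as genotype is, others still gave 9 and 11 lists, so chance cannot be excluded for the list calls over all stages. At unadjusted p under 0.05 genotype gave 695 genes, and of the 33 other splits 27 gave fewer and 6 gave more. The highest gave 2393, which points to structure of the samples, but that split puts both E12.5 libraries on 1 side. Among the balanced splits the highest gave 1031.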
